A study of Rattus norvegicus with 90 samples.

How the data were processed

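Microglia from the brains of male Wistar Han rats were measured by RNA sequencing in 90 libraries, 15 in each of 6 experiments (collection at P7, P12 or P22, with the intranasal or the intravenous route). Per the labels' protocols, pups received IL-1β or PBS by intraperitoneal injection in the first days after birth. HuMSC or sham followed, and the perfused brains, without olfactory bulbs and cerebellum, were dissociated and enriched for CD11b/c-positive cells. PolyA RNA from 100 ng of total RNA went into stranded libraries, sequenced as 75 bp single reads, per the labels' protocols. The protocols state 27 ± 7 M filtered reads per sample and an RNA quality above 7. Per the submitters' processing notes, which list tools without an order, STAR 2.7.2d, SAMtools, HTSeq 0.5.3 and DESeq2 1.8.1 were used. Neither the genome build nor the annotation is given in the sources used here. The values analysed were the raw read counts per gene deposited by the authors, whole numbers in every one of the 90 columns, without normalization. How HTSeq treated strand and reads shared by several genes is not given in the sources used here, so counts of genes with near-identical copies, such as the class II, mast cell protease and haemoglobin genes, are uncertain.

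Total counts per library ran from 11.5 to 42.5 M. By experiment the lowest, median and highest were 15.1, 19.4 and 26.2 M for P7 intranasal, 13.4, 21.3 and 34.3 for P7 intravenous and 11.5, 13.0 and 15.9 for P12 intranasal. They were 13.4, 18.9 and 42.5 M for P12 intravenous, 14.6, 18.5 and 26.1 for P22 intranasal and 16.2, 20.4 and 24.4 for P22 intravenous. Normalization factors lay between 0.918 and 1.05, the share of mitochondrially encoded counts between 0.487 and 15.4 percent, and that of the 10 most abundant genes between 5.88 and 16.2 percent. No pair of libraries was a duplicate. Nothing in the labels says that the replicates of a group are separate animals, so the p-values measure the spread between samples.

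The choices below were made before the data were examined, unless said otherwise. Per experiment, the 15 libraries were fitted together in edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with a mean per group. Genes passed filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and contrasts were tested with the quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05. The contrasts were injured minus control, each dose minus injured, the mean of the 3 doses minus injured and minus control, and a joint test among doses. The SE of a log2 fold change is its size over the square root of F. Differences of injury effects between routes and between ages came from 1 fit of the 36 control and injured libraries (12 group means), and differences of treatment effects between routes from the 30 libraries of an age. Run differences that add to both groups cancel in these contrasts. Control groups were compared between P22 and P7 in the 36-library fit, and genes called in the same direction in both routes were counted.

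Genes named in the text follow a rule with 3 parts. In each comparison, part (a) takes the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 1, a symbol that is not provisional, and all libraries of one group above all of the other (which chance gives for 10 percent of genes with 3 against 3). Part (b) takes up to 4 members with the smallest p of each gene list, and part (c) the genes P2ry12, Tmem119, Cx3cr1, Il1b, Tnf, Nos2, Ptgs2, Arg1, Mrc1, Igf1, Lgals3, Il1rn, Socs3, Spp1 and Mki67. The text prints a part of these in rank order, and comparisons with fewer than 10 called genes may name any of them. The 4 genes named for the test among doses at P12 and the most abundant marker of a cell type were chosen after their values were seen.

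The 19 gene lists were homeostatic microglia, inflammatory cytokines and NF-kB targets, cytotoxic or pro-inflammatory activation markers, repair or anti-inflammatory activation markers, immunoregulatory activation markers, interferon response, cell cycle, disease-associated and axon-tract microglia, antigen presentation, complement and phagocytosis, cholesterol synthesis, LXR targets and lipid efflux, glycolysis and hypoxia, oxidative phosphorylation, ribosomal proteins, immediate early and dissociation response, glucocorticoid response, mitochondrially encoded transcripts and microglial maturation markers. A further 16 lists held markers of other cells the beads could carry over: border-associated macrophage, monocyte, neutrophil, T and NK cell, B cell, dendritic cell, erythroid cell, neuron, astrocyte, oligodendrocyte precursor, oligodendrocyte, endothelial cell, mural cell, fibroblast, ependymal and choroid plexus, and mast cell. Of their 740 genes 706 were matched to the table by symbol or, for 10, by a synonym, and the others were not analysed here. 31 of the genes stand in more than 1 list. Members were counted at an adjusted p under 0.05 over all genes and adjusted over the list alone. Lists with at least 3 tested genes were tested with camera at a preset correlation of 0.01 and again with an estimated one, and with fry.

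The injury score of a library was the mean log2 CPM (prior count 2) of 100 genes minus that of 100 others. These were the genes of smallest p in each direction in injured against control of the other route at the same age. Scores were compared in R with two-sided exact permutation tests, with a smallest p of 0.1 for 3 against 3 and 0.00455 for 9 against 3. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9. Correlations of log2 fold changes across genes were set against 999 permutations of the library labels. The covariance that shared injured libraries produce was taken from 20 simulations of treated groups without an effect.

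The alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, the replicate number as a block, a fit of only the 2 groups compared, and leaving out each library in turn (each replicate number of every group in the joint fits). For the score they were 50 or 200 genes, RLE size factors and genes chosen at another age, and for correlations genes with a mean log2 CPM of at least 3. After the marker levels had been seen, fits without the 4 libraries whose neuron markers lay at least 1.5 log2 units above the median of their experiment were added. Other splits of the same libraries were refitted, all 10 for 3 against 3 and 21 drawn ones, the real one included, for the rest. The fits were tested on simulated counts in which 200 genes were changed by known folds. In the simulated injured against control comparison at P7 in the intranasal experiment (13872 genes), edgeR called 23.9, 70.15 and 92.4 percent of genes changed 1.5-, 2- and 4-fold.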

Results

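Microglia, the resident macrophages of the brain, were enriched from male Wistar Han rats with beads against CD11b/c, and their polyadenylated RNA was sequenced. The pups had received recombinant mouse IL-1β at 20 µg per kg, a model of neonatal systemic inflammation, or PBS. Human umbilical cord mesenchymal stromal cells (HuMSC), studied for the immunoregulatory factors they secrete, or a sham followed through the nose or a vein. Brains were collected 48 h after the cells, at postnatal day (P) 7, 12 or 22. The 90 libraries made 30 groups of 3. Each of the 6 experiments, which join 1 age and 1 route, had a control group (PBS and sham), an injured group (IL-1β and sham) and 3 treated groups given IL-1β and 20, 50 or 125 M cells per kg (HuMSC20, HuMSC50 and HuMSC125). The series set out to score these 18 treatment protocols by the microglial transcriptome. Every experiment was sequenced as a run of its own, and the P7 brains were dissociated with another kit than the older ones, so levels at different ages or routes cannot be told apart from runs. Groups were therefore compared within a run.

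Total counts had a median of 18.9 M per library and were lowest at P12 in the intranasal experiment. Of 32623 genes, between 13594 and 14698 were tested per experiment. Across genes, log2 CPM of 2 libraries of a group correlated with r from 0.955 to 0.993. The cytokine gene Tnf had 3 counts over all 90 libraries and could not be tested, Nos2 was not analysed here, and Arg1 passed the filter on low counts only at P7 in the intravenous experiment. Neuron markers stood apart in 4 libraries, whose mean marker level was at least 1.5 log2 units above the median of their experiment. At P7 in the intravenous experiment these were HuMSC20 replicate 1 (2.46 above), HuMSC125 replicate 1 (2.36) and HuMSC125 replicate 2 (2.46), and at P12 in the intranasal experiment HuMSC125 replicate 2 (1.95).

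**Figure D1:**
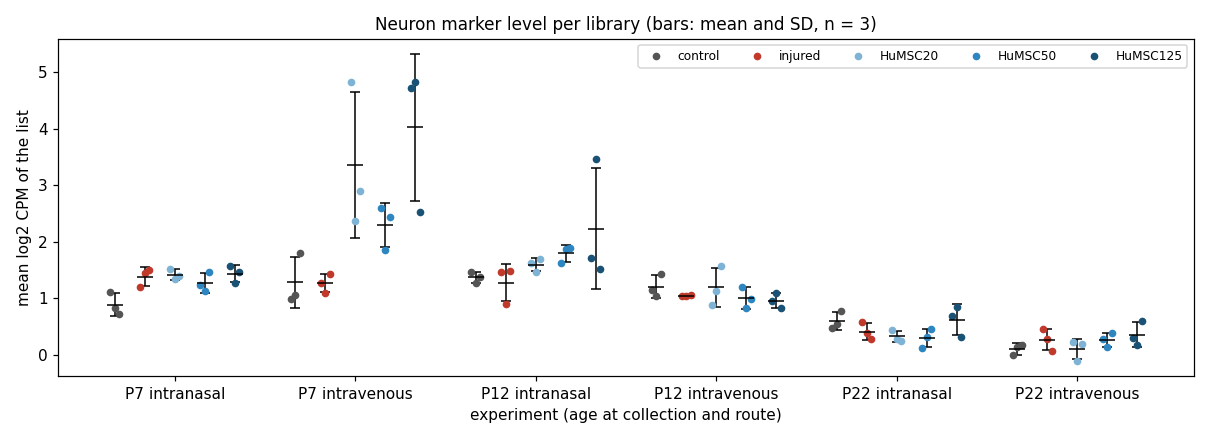
Mean log2 CPM of the neuron markers (y axis) in each library, by experiment (x axis) and arm (colour); points are libraries, and dashes with bars are the mean and SD of 3. HuMSC125 replicate 2 at P7 in the intravenous experiment had a mean of 4.82.

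The comparison of injured with control animals asked what IL-1β had left in the microglial transcriptome at each age. At P7 in the intranasal experiment, 33 of 43 cell cycle genes fell in injured libraries and 0 rose. The mitotic genes Kif20a, Cdc20 and Tpx2 fell by 1.10 ± 0.14, 1.05 ± 0.15 and 1.03 ± 0.16 on the log2 scale (± SE, n = 3 against 3), and the proliferation marker Mki67 by 0.88 ± 0.16. In the same libraries 10 of 25 cholesterol synthesis genes fell, among them the pathway enzyme gene Msmo1 (fell by 0.79 ± 0.11). Counts adjusted over the list alone were 37 and 14. Camera gave adjusted p = 5.18e-45 and 4.15e-14 for the 2 lists, and adjusted p = 0.116 and 0.115 with an estimated correlation. The deepest fall was that of Ankrd55, a gene in human autoimmune risk loci, by 3.42 ± 0.34 (edgeR adjusted p = 0.000135). It went from 79.8 ± 0.626 CPM in control to 7.45 ± 0.586 CPM in injured libraries (SD, n = 3). Enpp6, a choline phosphodiesterase of newly formed oligodendrocytes, and Il6st, the signalling subunit of the IL-6 receptor family, fell by 2.80 ± 0.28 and 1.98 ± 0.25.

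Among rising genes in that comparison, the T cell chemokine Ccl5 led with 3.80 ± 0.81 (edgeR adjusted p = 0.0132), which became 0.0607 without injured replicate 1, 0.0515 without control replicate 1 and 0.0507 without control replicate 2. The class II genes RT1-Ba and RT1-Da rose by 1.20 ± 0.23 and 1.17 ± 0.23, within 4 risen antigen presentation genes of 20 (5 adjusted over the list alone). The list's median was -0.06, while its camera test pointed up (adjusted p = 0.348). The transcription factor genes Fosl2 and Nr4a2 rose by 1.63 ± 0.22 and 1.57 ± 0.22, with 5 immediate early genes of 32 rising and 3 falling (10 and 4 adjusted over the list alone, adjusted p = 0.544 with an estimated correlation). Homeostatic microglial genes went both ways, with 1 of 25 rising and 3 falling (2 and 6 alone, adjusted p = 0.356 with an estimated correlation), among them Crybb1 (fell by 1.35 ± 0.24) and the fructose transporter Slc2a5 (fell by 0.62 ± 0.11). The identity genes P2ry12, Tmem119 and Cx3cr1 did not pass the test, at -0.19 ± 0.11, -0.15 ± 0.29 and -0.02 ± 0.13. Markers of blood-borne cells moved beside these genes. Of 15 neutrophil markers 5 rose (11 adjusted over the list alone), and of 11 mast cell markers 4 (9 alone), with adjusted p = 0.356 and 0.295 with an estimated correlation. Monocyte markers averaged 4.27 to 4.43 log2 CPM in injured and 3.70 to 3.75 in control libraries, and T and NK ones 0.99 to 1.90 and 0.75 to 0.87. B cell markers fell by 0.67 ± 0.17. In all, edgeR called 772 of 13872 genes, 371 higher and 401 lower. The count was 231 without injured replicate 3, 364 without injured replicate 1 and 377 without control replicate 2.

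In the intravenous experiment at P7 edgeR called 5 genes in injured against control. Ankrd55 fell by 2.57 ± 0.21 (adjusted p = 0.000143), from 63.5 ± 5.19 to 10.7 ± 2.98 CPM (SD, n = 3), and the heparan sulfate proteoglycan gene Sdc1 rose by 1.65 ± 0.16. Nr4a2 rose by 1.61 ± 0.24, and Ccdc8 fell by 1.43 ± 0.20. The count was 2 without injured replicate 1 or 2 or control replicate 1, 2 or 3. For Nr4a2 the adjusted p became 0.197 without injured replicate 1, 0.189 without injured replicate 2, 0.322 without control replicate 1, 0.226 without control replicate 2 and 0.134 without control replicate 3, and for Ccdc8 0.197 without injured replicate 1, 0.189 without injured replicate 2, 0.131 without control replicate 1, 0.0676 without control replicate 2 and 0.134 without control replicate 3. All 5 genes were also called in the intranasal experiment, and of the 768 genes called there and tested in both, 700 (91.2%) had the same sign in the intravenous one. The change of Mki67 was -0.08 ± 0.20, and no cell cycle gene was called. Of 20 antigen presentation genes 0 rose over all genes and 6 adjusted over the list alone (camera adjusted p = 2.29e-09, adjusted p = 0.326 with an estimated correlation). The test of the difference between routes at P7 called 0 genes with edgeR, with 734 at an unadjusted p under 0.05 and 63 by DESeq2. As a list, cell cycle genes differed between the routes, with a median of 0.78 (intravenous minus intranasal), 36 of 43 higher adjusted over the list alone, and adjusted p = 0.000257 with an estimated correlation. Neutrophil and mast cell markers differed the other way, with medians of -1.79 and -2.25 (adjusted p = 0.0349 and 0.0172 with an estimated correlation).

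**Figure D2:**
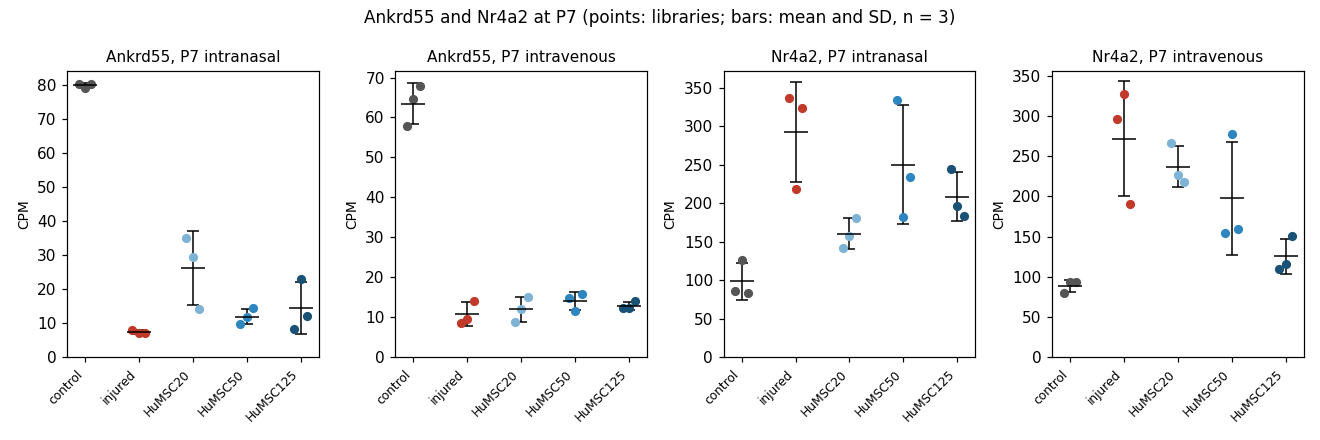
CPM (y axis) of Ankrd55 and Nr4a2 by arm (x axis) in the intranasal and intravenous experiments at P7; points are libraries, and dashes with bars are the mean and SD of 3. Nr4a2 went from 98.9 to 293 CPM between control and injured in the intranasal experiment and from 89.0 to 271 CPM in the intravenous one.

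At P12 in the intranasal experiment, 9 of 17 oligodendrocyte markers fell in injured libraries (15 adjusted over the list alone), among them the myelin genes Mobp (fell by 1.79 ± 0.23) and Mog (fell by 1.98 ± 0.26, n = 3 against 3). This list held with an estimated correlation (adjusted p = 0.0181). Csf1, the growth factor that microglia depend on, rose by 1.22 ± 0.11 (edgeR adjusted p = 0.000199), and the lipid droplet gene Plin2 by 0.81 ± 0.11. They were among 6 disease-associated genes of 29 that rose, 8 adjusted over the list alone (adjusted p = 0.196 with an estimated correlation). Of 32 immediate early genes 7 rose, with Fosl2 at 1.30 ± 0.19, and 17 did so adjusted over the list alone (adjusted p = 0.254 with an estimated correlation). The cytotoxic T cell marker Cd8a rose by 2.43 ± 0.43, with an adjusted p of 0.0508 without control replicate 1 and 0.0634 without control replicate 2. The calcium-binding protein gene Cabp7 and the potassium channel subunit gene Dpp6 fell by 2.34 ± 0.26 and 2.10 ± 0.30. Mural cell markers fell too, 5 of 12 (9 alone), with Tagln at -1.02 ± 0.15 (adjusted p = 0.193 with an estimated correlation). Il1b itself missed the threshold of edgeR at 1.18 ± 0.32 (adjusted p = 0.0601) and passed that of DESeq2 (adjusted p = 0.0495). In all 383 genes were called, 222 higher and 161 lower, and the count was 68 without control replicate 2, 86 without injured replicate 1, 96 without control replicate 1 and 214 without injured replicate 2.

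At P12 in the intravenous experiment edgeR called 2 genes in injured against control, the T cell surface genes Cd5 (fell by 1.06 ± 0.12) and Lag3 (fell by 0.89 ± 0.13). The count was 0 without injured replicate 1 or 3, 1 without control replicate 3 and 6 without injured replicate 2 or control replicate 1. Adjusted p for Cd5 was 0.0555 without injured replicate 1 and 0.0666 without injured replicate 3, and for Lag3 0.176 without injured replicate 1, 0.101 without injured replicate 2, 0.213 without injured replicate 3, 0.101 without control replicate 2 and 0.126 without control replicate 3. Of 381 genes called in the intranasal experiment at P12 and tested in both, 193 (50.7%) had the same sign in the intravenous one. Erythroid markers had a median of 1.66, with 0 of 7 called over all genes and 5 adjusted over the list alone (adjusted p = 0.799 with an estimated correlation). The difference between routes at P12 was called for 28 genes, 9 higher in the intravenous experiment and 19 lower. The myelin gene Mobp differed by 2.02 ± 0.42, and Cd8a and the synaptic immediate early gene Arc by -2.18 ± 0.48 and -1.90 ± 0.37 (log2 difference of injury effects ± SE, 3 libraries per group). The count was 1 without replicate 1 or without replicate 2 of every group, and 0 without replicate 3.

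At P22 edgeR called few genes in injured against control. In the intranasal experiment edgeR called 0 genes, with 646 at an unadjusted p under 0.05 and 7 by DESeq2, and the count was 1 without injured replicate 3 or control replicate 2. Of 9 mast cell markers 3 rose adjusted over the list alone and 0 over all genes (adjusted p = 0.200 with an estimated correlation). In the intravenous experiment the steroid receptor coactivator gene Ncoa3 fell by 0.78 ± 0.09 (adjusted p = 0.00493; 0.0810 without injured replicate 1, 0.0937 without injured replicate 2 and 0.0628 without control replicate 1) as the 1 gene called, with 2080 at an unadjusted p under 0.05 and 191 called by DESeq2. The count was 0 without injured replicate 1 or 2 or control replicate 1 and 7 without control replicate 3. Mural cell and fibroblast markers had medians of 0.94 and 0.82, with 11 of 12 and 8 of 12 higher adjusted over the list alone and none over all genes (adjusted p = 0.668 and 0.668 with an estimated correlation). The difference between routes at P22 was called for 0 genes by edgeR and 0 by DESeq2, with 1196 at an unadjusted p under 0.05, and for 11 by edgeR without replicate 3 of every group.

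The size of the injury effect was then compared between ages over both routes. Ankrd55, which fell at P7, had an injury effect 2.39 ± 0.23 log2 units higher at P12 than at P7, and 2.76 ± 0.23 higher at P22 than at P7 (3 libraries per group). The injury effect on cell cycle genes was also higher at later ages than at P7, and the difference was called for 27 of 43 cell cycle genes at P12 (35 adjusted over the list alone, adjusted p = 0.000877 with an estimated correlation). At P22 it was called for 10 (24 alone, adjusted p = 0.265 with an estimated correlation). Ccl5 led the opposite direction at P12, at -2.44 ± 0.60. Between P12 and P22 the injury effects on Cabp7, Mbp and Cblb differed by 1.65 ± 0.24, 0.96 ± 0.18 and -0.69 ± 0.12. edgeR called 169 genes for P12 against P7 (12, 21 and 22 without replicate 1, 2 and 3 of every group) and 320 for P22 against P7 (28, 39 and 58). It called 3 for P22 against P12 (0, 0 and 1).

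**Figure D3:**
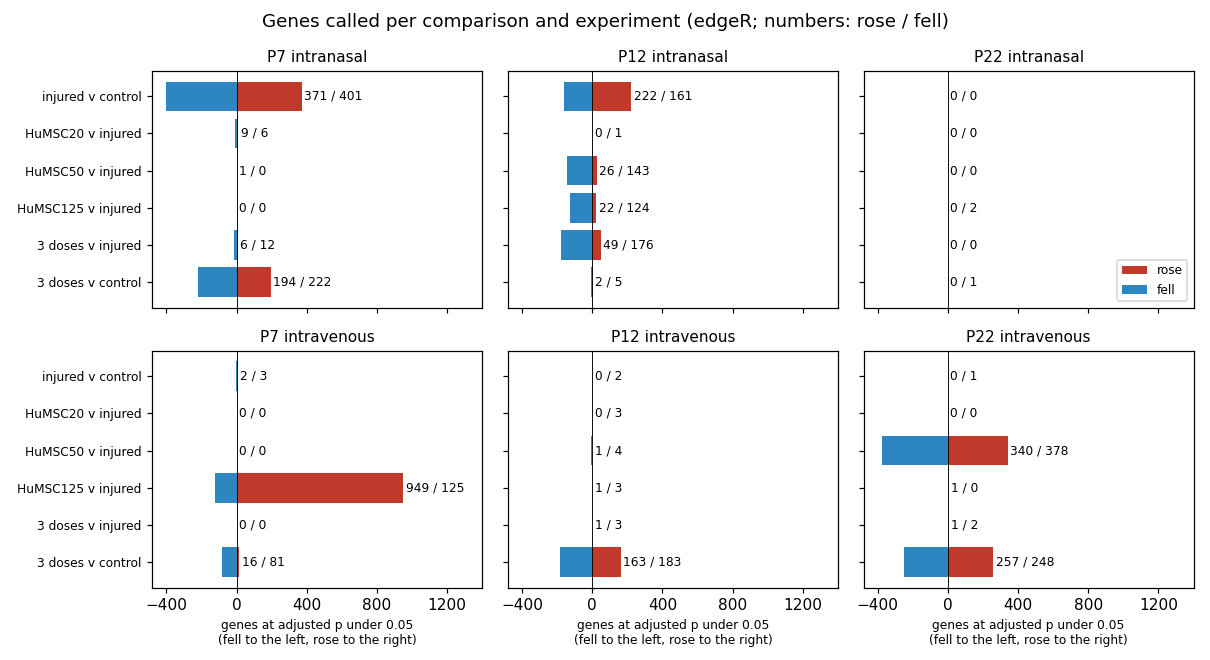
Genes called by edgeR at adjusted p under 0.05 (x axis; fell to the left, rose to the right) per comparison (y axis) and experiment (panels). HuMSC125 against injured at P7 in the intravenous experiment had the longest bar to the right, 949 genes.

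Treated animals were compared with the injured animals of their own experiment, to ask how each protocol moved the microglia. In the intranasal experiment at P7, Enpp6, which fell with injury, rose by 1.66 ± 0.25 over the mean of 3 doses (n = 9 against 3, edgeR adjusted p = 0.0211), and the transcription factor gene Egr2 by 0.61 ± 0.08 (adjusted p = 0.0118). The ephrin receptor gene Ephb3 fell by 1.14 ± 0.15. Their adjusted p became 0.136 without injured replicate 1, 0.0509 without injured replicate 2 and 0.177 without injured replicate 3 for Enpp6, 0.127 without injured replicate 1 and 0.162 without injured replicate 3 for Egr2, and 0.177 without injured replicate 3 for Ephb3. No cell cycle gene of 43 was called over all genes, while 31 rose adjusted over the list alone, with a median of 0.39 (camera adjusted p = 4.38e-29, adjusted p = 0.257 with an estimated correlation). With HuMSC20 alone Enpp6 rose by 2.24 ± 0.28 (adjusted p of 0.0884 without injured replicate 1 and 0.0955 without injured replicate 3), and with HuMSC50 Egr2 was the only gene called, at 0.72 ± 0.09 (adjusted p of 0.224 without injured replicate 1, 0.0797 without injured replicate 2, 0.203 without injured replicate 3, 0.0868 without HuMSC50 replicate 1 and 0.142 without HuMSC50 replicate 3). edgeR called 18 genes over the mean of doses, a count that was 0 without injured replicate 3, 1 without injured replicate 1, 4 without HuMSC20 replicate 2, 10 without HuMSC20 replicate 3 and 11 without injured replicate 2. It called 15 for HuMSC20, which was 0 without injured replicate 1 or 3, 1 without HuMSC20 replicate 2, 2 without HuMSC20 replicate 3 and 4 without HuMSC20 replicate 1, and 1 for HuMSC50, which was 0 without injured replicate 1, 2 or 3 or HuMSC50 replicate 1 or 3 and 3 without HuMSC50 replicate 2. For HuMSC125 it called 0, with 1029 at an unadjusted p under 0.05 and 47 by DESeq2. Differences among doses were called for 0 genes (756 unadjusted, 6 by DESeq2), a count that was 1 without HuMSC50 replicate 2 and 3 without HuMSC20 replicate 1.

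Against control, the treated libraries of that experiment still had lower Ankrd55 (fell by 2.27 ± 0.23, n = 9 against 3) and Ccdc8 (fell by 1.51 ± 0.17). Cell cycle genes were lower for 14 of 43 (33 adjusted over the list alone) and cholesterol synthesis genes for 6 of 25 (9 alone), with Msmo1 at -0.64 ± 0.09 (adjusted p = 0.225 and 0.200 with an estimated correlation). Mast cell markers were higher for 7 of 11 (9 alone, adjusted p = 0.200 with an estimated correlation), with a median of 2.10. edgeR called 416 genes, 194 higher and 222 lower, and the count was 59 without control replicate 2, 177 without control replicate 1, 201 without HuMSC20 replicate 2, 239 without control replicate 3 and 243 without HuMSC125 replicate 3.

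HuMSC125 at P7 in the intravenous experiment differed from injured by transcripts of other brain cells. Neuron markers rose for 21 of 23 (23 adjusted over the list alone), oligodendrocyte precursor markers for 11 of 12 (12) and oligodendrocyte markers for 9 of 16 (12), with adjusted p = 0.163, 0.165 and 0.196 with an estimated correlation. The neuronal scaffold gene Akap6 rose by 5.11 ± 0.90, and the axonal motor gene Kif1a by 4.81 ± 0.91 (n = 3 against 3). HuMSC125 replicates 1 and 2 were 2 of the libraries rich in neuron markers, and the third had a lower level. The mitochondrially encoded share of counts was 13.6, 15.4 and 6.14 percent in HuMSC125 replicates 1, 2 and 3, against 4.16 to 5.86 in injured libraries, and 10.3, 4.55 and 8.77 in those of HuMSC20 and 9.46, 6.12 and 0.487 in those of HuMSC50. Inflammatory genes were lower in HuMSC125, 9 of 28 (17 alone, adjusted p = 0.122 with an estimated correlation), with the interferon-induced chemokine Cxcl10 at -1.08 ± 0.18. edgeR called 1074 genes, 949 higher and 125 lower, at HuMSC125. The count was 0 without injured replicate 1 or 2 or HuMSC125 replicate 1 or 2, 6 without injured replicate 3 and 2127 without HuMSC125 replicate 3. Without the neuron-rich libraries 1 HuMSC125 library was left, so no count is given for that fit. Adjusted p for Akap6, Kif1a and Cxcl10 alike became 0.106 without injured replicate 1, 0.129 without injured replicate 2, 0.0742 without injured replicate 3, 0.0895 without HuMSC125 replicate 1 and 0.108 without HuMSC125 replicate 2.

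The other doses at P7 in the intravenous experiment gave 0 called genes for HuMSC20 with edgeR (2099 at an unadjusted p under 0.05, 756 by DESeq2) and 0 for HuMSC50 (876 and 17). The counts were 662 without HuMSC20 replicate 2, and 1 without HuMSC50 replicate 2. Over the mean of doses 0 genes were called (2356 unadjusted, 1048 by DESeq2), a count that was 2 without HuMSC50 replicate 2, 477 without HuMSC20 replicate 2 and 1040 without HuMSC125 replicate 3. Glucocorticoid response genes were nevertheless lower as a list, beside the mitochondrial shares above, with a median of -0.38, 0 of 16 called over all genes and 5 adjusted over the list alone, and held with an estimated correlation (adjusted p = 0.0424). Inflammatory genes had a median of -0.39, with 15 of 28 lower adjusted over the list alone (adjusted p = 0.0964 with an estimated correlation), beside neuron markers with a median of 2.48 (22 of 23 higher alone, adjusted p = 0.156 with an estimated correlation). Differences among doses were called for 0 genes (1875 unadjusted, 21 by DESeq2), and for 1 without HuMSC20 replicate 3. Against control, Ankrd55 fell by 2.29 ± 0.15 (n = 9 against 3), the glucocorticoid-induced kinase gene Sgk1 by 1.54 ± 0.13 and Pdk4, which restrains glucose oxidation, by 1.21 ± 0.15. Of 43 cell cycle genes 3 fell (30 adjusted over the list alone, adjusted p = 0.280 with an estimated correlation). edgeR called 97 genes against control, 16 higher and 81 lower. That count was 14 without control replicate 1, 15 without control replicate 2 or 3, 47 without HuMSC125 replicate 2, 52 without HuMSC125 replicate 1, 423 without HuMSC50 replicate 3, 546 without HuMSC20 replicate 2 and 1242 without HuMSC125 replicate 3.

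At P12 in the intranasal experiment, inflammatory and disease-associated genes were lower over the mean of doses than in injured libraries, 10 of 29 (17 adjusted over the list alone) and 10 of 29 (12 alone). Both lists held with an estimated correlation (adjusted p = 0.0499 and 0.0499). Csf1 fell by 1.26 ± 0.09 over the mean of doses (n = 9 against 3, edgeR adjusted p = 2.46e-06), and the melanosomal glycoprotein gene Gpnmb by 1.13 ± 0.18. Pdk4 fell by 1.68 ± 0.18, the stress-induced Gadd45b by 1.16 ± 0.16 and Cd8a by 1.82 ± 0.30. The mitochondrially encoded share was 2.81, 7.54 and 6.73 percent in HuMSC50 replicates 1, 2 and 3, 5.35 to 7.13 in HuMSC125 and 3.85 to 4.19 in HuMSC20, against 3.10 to 4.45 in injured and 4.56 to 5.84 in control libraries. Oligodendrocyte markers rose in the same libraries, 5 of 17 (12 alone, adjusted p = 0.0499 with an estimated correlation). The myelin gene Cldn11 rose by 0.82 ± 0.14 (adjusted p = 0.0691 without injured replicate 1). Neutrophil markers fell for 4 of 16 (7 alone, adjusted p = 0.0535 with an estimated correlation). Of the 383 genes called in injured against control and the 225 called here (49 higher, 176 lower), 128 were common, all 128 in opposite directions, where independent lists would share 3.39 in that way. Both comparisons use the same 3 injured libraries, which cannot be split, so part of this excess can come from them. The covariance of the effects across genes was -0.0788, against -0.0353 on average when treated groups were simulated without any effect. Those simulations drew each gene independently. The count of 225 was 41 without injured replicate 1, 84 without injured replicate 2, 122 without HuMSC50 replicate 2, 130 without HuMSC50 replicate 3, 144 without HuMSC20 replicate 1 and 146 without HuMSC20 replicate 3.

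The 3 doses at P12 in the intranasal experiment were compared in the test among doses, which called Csf1, Pdk4, Il1b and Mobp among others (named after their values were seen). Csf1 stood at 61.1 CPM with HuMSC20, 28.1 with HuMSC50 and 28.8 with HuMSC125, against 88.1 in injured and 37.8 in control libraries (means, n = 3). With HuMSC50 Csf1 fell by 1.65 ± 0.12 and Pdk4 by 2.47 ± 0.26, and the monocyte chemokine Ccl2 by 1.43 ± 0.21. Mobp rose by 1.68 ± 0.23. With HuMSC125 Csf1 fell by 1.61 ± 0.11 and Pdk4 by 2.03 ± 0.25. Il1b fell by 1.57 ± 0.32 with HuMSC50 and by 1.58 ± 0.32 with HuMSC125. Its adjusted p became 0.132 without injured replicate 1, 0.149 without HuMSC50 replicate 2 and 0.142 without HuMSC50 replicate 3 at the former dose, and 0.148 without injured replicate 1, 0.0886 without HuMSC125 replicate 1 and 0.0989 without HuMSC125 replicate 3 at the latter. Inflammatory genes fell for 13 of 29 with HuMSC50 and 9 with HuMSC125 (17 and 17 adjusted over the list alone, adjusted p = 0.0244 and 0.0490 with an estimated correlation).

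In edgeR's counts at P12 in the intranasal experiment, HuMSC50 had 169 called genes (26 higher, 143 lower) and HuMSC125 146 (22 and 124). For HuMSC50 the count was 29 without HuMSC50 replicate 2, 34 without HuMSC50 replicate 3, 57 without injured replicate 1, 99 without HuMSC50 replicate 1 and 109 without injured replicate 2. For HuMSC125 it was 28 without injured replicate 1, 56 without HuMSC125 replicate 3, 63 without HuMSC125 replicate 1 and 87 without injured replicate 2, and 3 in a fit of the 2 groups alone. For HuMSC20 the 1 gene became 0 without injured replicate 1, 2 or 3 or HuMSC20 replicate 1 and 3 without HuMSC20 replicate 2. The 33 genes called among doses became 2 without HuMSC20 replicate 3, 4 without HuMSC20 replicate 2 or HuMSC50 replicate 2, 6 without HuMSC50 replicate 3, 12 without HuMSC125 replicate 3, 21 without HuMSC20 replicate 1 and 66 without HuMSC125 replicate 2. Against control 7 genes were called, led by the fall of Dpp6 (by 1.56 ± 0.22, n = 9 against 3), with 2 of 17 oligodendrocyte markers lower (10 adjusted over the list alone, adjusted p = 0.128 with an estimated correlation). That count was 0 without HuMSC50 replicate 1 or control replicate 1 or 2, 1 without HuMSC20 replicate 2, 3 without HuMSC20 replicate 1, HuMSC50 replicate 2 or control replicate 3 and 4 without HuMSC20 replicate 3. Adjusted p for Dpp6 was 0.0550 without HuMSC50 replicate 1, 0.0763 without control replicate 1 and 0.149 without control replicate 2.

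**Figure D4:**
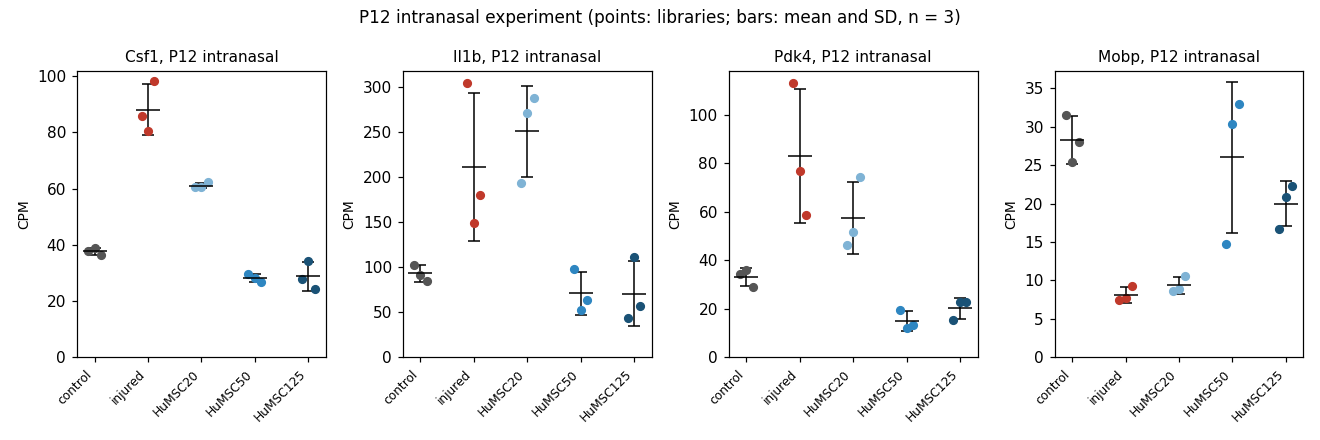
CPM (y axis) of Csf1, Il1b, Pdk4 and Mobp by arm (x axis) at P12 in the intranasal experiment; points are libraries, and dashes with bars are the mean and SD of 3. Il1b averaged 211 CPM in injured, 250 CPM in HuMSC20, 70.9 CPM in HuMSC50 and 70.6 CPM in HuMSC125 libraries.

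At P12 in the intravenous experiment the astrocyte membrane protein gene Mlc1 fell by 0.80 ± 0.08 over the mean of doses (n = 9 against 3, edgeR adjusted p = 0.000615), and P2rx4, an ATP-gated channel of microglia, by 0.66 ± 0.07. Mlc1 fell at each dose, by 0.80 ± 0.10, 0.85 ± 0.10 and 0.75 ± 0.10 with HuMSC20, HuMSC50 and HuMSC125. Astrocyte markers were lower as a list, 1 of 16 over all genes and 12 adjusted over the list alone, with a median of -0.49 (adjusted p = 0.0281 with an estimated correlation). Erythroid markers had a median of -2.39, and 5 of 7 were lower adjusted over the list alone (adjusted p = 0.233 with an estimated correlation). edgeR called 4 genes over the mean of doses, which became 7 without injured replicate 2 or HuMSC20 replicate 3, 8 without HuMSC20 replicate 1, 14 without HuMSC50 replicate 1, 16 without HuMSC125 replicate 3 and 19 without HuMSC20 replicate 2. It called 3 for HuMSC20 (0 without HuMSC20 replicate 1 or 2 and 5 without injured replicate 2) and 5 for HuMSC50 (0 without HuMSC50 replicate 3, 9 without injured replicate 1, 10 without injured replicate 2 and 12 without HuMSC50 replicate 1). For HuMSC125 it called 4 (0 without injured replicate 3 or HuMSC125 replicate 1, 2 or 3 and 1 without injured replicate 1), and among doses 1 (0 without HuMSC20 replicate 1, 2 or 3 or HuMSC50 replicate 2 or 3, 2 without HuMSC125 replicate 1 or 2, 3 without HuMSC50 replicate 1 and 4 without HuMSC125 replicate 3). Adjusted p for Mlc1 was 0.104 without HuMSC20 replicate 1 and 0.0724 without HuMSC20 replicate 2 at HuMSC20, 0.0706 without HuMSC50 replicate 3 at HuMSC50 and 0.0548 without injured replicate 2, 0.116 without injured replicate 3, 0.103 without HuMSC125 replicate 1, 0.179 without HuMSC125 replicate 2 and 0.0851 without HuMSC125 replicate 3 at HuMSC125.

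Against control in that experiment the astrocyte genes Mlc1, S100b and Aldoc fell by 0.97 ± 0.08, 0.62 ± 0.10 and 0.54 ± 0.11 (n = 9 against 3), within 7 of 16 astrocyte markers (8 adjusted over the list alone, adjusted p = 0.198 with an estimated correlation). Hspa1b, a heat shock protein gene, rose by 1.92 ± 0.31, Il1rn, the antagonist of the IL-1 receptor, by 1.11 ± 0.19, and Insig1, a sterol sensor, by 0.45 ± 0.07. edgeR called 346 genes, 163 higher and 183 lower, and the count was 26 without control replicate 2, 108 without HuMSC50 replicate 3, 169 without HuMSC125 replicate 2, 191 without HuMSC125 replicate 3, 212 without HuMSC20 replicate 1, 224 without HuMSC50 replicate 1 and 749 without control replicate 1. Without control replicate 2, adjusted p was 0.0822 for S100b, 0.145 for Aldoc, 0.0610 for Hspa1b, 0.0844 for Il1rn and 0.0619 for Insig1.

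At P22 in the intranasal experiment the immediate early genes Arc and Apold1 were lower with HuMSC125 than in injured libraries, Arc by 1.55 ± 0.19 (n = 3 against 3, edgeR adjusted p = 0.0147), and Apold1 by 1.801 ± 0.26, and they were the 2 genes called. Adjusted p became 0.102 without injured replicate 2, 0.0780 without HuMSC125 replicate 1, 0.151 without HuMSC125 replicate 2 and 0.138 without HuMSC125 replicate 3 for Arc and 0.106 without injured replicate 1, 0.102 without injured replicate 2, 0.0864 without HuMSC125 replicate 1, 0.332 without HuMSC125 replicate 2 and 0.250 without HuMSC125 replicate 3 for Apold1. Against control Arc was the only gene called over the mean of doses, and fell by 1.59 ± 0.14 (n = 9 against 3). HuMSC20 and HuMSC50 each had 0 called genes with edgeR, against 1965 and 2238 at an unadjusted p under 0.05 and 20 and 20 by DESeq2. The mean of doses had 0 (2608 unadjusted, 147 by DESeq2), and the test among doses 0 (874 and 41). Ribosomal protein genes had a median of -0.27 over the mean of doses, with 17 of 37 lower adjusted over the list alone and none over all genes (camera adjusted p = 7.15e-10, adjusted p = 0.985 with an estimated correlation). The count for HuMSC125 was 0 without injured replicate 2 or HuMSC125 replicate 2 or 3, 1 without injured replicate 1 or HuMSC125 replicate 1 and 4 without injured replicate 3. For the mean of doses it was 1 without HuMSC20 replicate 2 and 7 without injured replicate 3, among doses 1 without HuMSC125 replicate 1, and against control 2 without HuMSC50 replicate 1 or 3 or control replicate 2 or 3 and 3 without HuMSC125 replicate 1.

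At P22 in the intravenous experiment ribosomal protein genes were lower with HuMSC50 than in injured libraries, 26 of 37 (34 adjusted over the list alone), with Rps20 at -0.94 ± 0.13 (n = 3 against 3, edgeR adjusted p = 0.00897). Oxidative phosphorylation genes fell for 8 of 45 (18 alone), neutrophil markers for 5 of 17 (7 alone), with Retnlg at -2.25 ± 0.32, T and NK cell markers for 3 of 13 (9 alone) and monocyte markers for 2 of 12 (4 alone). With an estimated correlation adjusted p = 0.450, 0.689, 0.450, 0.450 and 0.689 for the 5 lists. Ncoa3, which fell with injury, rose by 0.67 ± 0.09 with HuMSC125. edgeR called 718 genes for HuMSC50, 340 higher and 378 lower. The count was 1 without HuMSC50 replicate 2, 2 without injured replicate 2 or 3, 23 without HuMSC50 replicate 3 and 138 without injured replicate 1. HuMSC20 had 0 called genes (557 at an unadjusted p under 0.05, 4 by DESeq2). HuMSC125 had 1, which became 0 without injured replicate 1, 2 or 3 or HuMSC125 replicate 2 and 2 without HuMSC125 replicate 3, and the mean of doses 3, which became 0 without injured replicate 2 or 3, HuMSC20 replicate 1, 2 or 3, HuMSC50 replicate 3 or HuMSC125 replicate 2, 1 without injured replicate 1, HuMSC50 replicate 2 or HuMSC125 replicate 1, 16 without HuMSC125 replicate 3 and 42 without HuMSC50 replicate 1. Among doses 1 gene, Ncoa3, was called, and 0 without HuMSC20 replicate 1, 2 or 3 and 83 without HuMSC125 replicate 3. Adjusted p for Rps20 became 0.0539 without injured replicate 2, 0.0534 without injured replicate 3 and 0.0691 without HuMSC50 replicate 2, and for Retnlg 0.0539 without injured replicate 2, 0.0534 without injured replicate 3 and 0.0742 without HuMSC50 replicate 2. For Ncoa3 it was 0.140 without injured replicate 1, 0.219 without injured replicate 2, 0.201 without injured replicate 3, 0.138 without HuMSC125 replicate 2 and 0.0525 without HuMSC125 replicate 3 at HuMSC125.

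Against control in the same experiment, vascular and fibroblast markers were higher in treated libraries, 6 of 12 fibroblast markers (12 adjusted over the list alone), 3 of 16 endothelial (12 alone) and 3 of 12 mural (9 alone), with adjusted p = 0.535, 0.535 and 0.535 with an estimated correlation. The collagen gene Col6a1 rose by 1.24 ± 0.25 and the tight junction gene Cldn5 by 0.91 ± 0.17 (n = 9 against 3, edgeR). Ifi44, an interferon-induced gene, fell by 0.59 ± 0.09. In all 505 genes were called, 257 higher and 248 lower, and the count was 4 without control replicate 1, 21 without HuMSC125 replicate 1, 57 without HuMSC50 replicate 2, 58 without control replicate 3, 127 without HuMSC125 replicate 3, 195 without HuMSC20 replicate 1, 244 without HuMSC50 replicate 1, 977 without HuMSC20 replicate 2 and 1043 without HuMSC125 replicate 2. Adjusted p for Col6a1 became 0.0554 without HuMSC50 replicate 2, 0.0562 without HuMSC125 replicate 1, 0.137 without control replicate 1 and 0.0775 without control replicate 3, for Cldn5 0.0511 without HuMSC50 replicate 2, 0.0536 without HuMSC125 replicate 1, 0.126 without control replicate 1 and 0.0716 without control replicate 3, and for Ifi44 0.101 without control replicate 1.

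The effect of treatment was then compared between routes at each age, over the mean of doses. At P12 the inflammatory genes were lower relative to injured with the intranasal route, with a median difference of 0.74 (intravenous minus intranasal), 2 of 29 called and 17 adjusted over the list alone (adjusted p = 0.0365 with an estimated correlation). The nuclear receptor gene Nr4a3 led with 2.31 ± 0.42, followed by the neutrophil collagenase gene Mmp8 with 2.23 ± 0.51. Astrocyte markers differed the other way, 7 of 16 (11 alone, adjusted p = 0.00706 with an estimated correlation). At P7 the neuronal gene Kif1a led the genes higher with the intravenous route (4.36 ± 0.78), and the nucleotide synthesis gene Rrm2 those higher with the intranasal one (-0.96 ± 0.19; 9 treated and 3 injured libraries per route). Of the 9 treated intravenous libraries there, 3 are neuron-rich. edgeR called 131 genes at P12, 53 higher and 78 lower, and the count was 29, 0 and 0 without replicate 1, 2 and 3 of every group. At P7 it called 25, which became 0 without any 1 replicate number. At P22 it called 0 genes, with 691 at an unadjusted p under 0.05 and 0 by DESeq2.

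An injury score placed each library by genes chosen in the injured and control libraries of the other route at the same age. The score is the mean log2 CPM of the 100 genes most clearly higher in injured libraries there minus that of the 100 lower. Control libraries at P7 in the intranasal experiment averaged -0.615 ± 0.0643 and injured ones 0.971 ± 0.199 (SD, n = 3). HuMSC20, HuMSC50 and HuMSC125 libraries averaged 0.158 ± 0.0794, 0.467 ± 0.0825 and 0.528 ± 0.219. Treated libraries lay 0.586 below injured ones (two-sided exact permutation p = 0.00455, the smallest that 9 against 3 can give, adjusted p = 0.0273 over 6 experiments). Without injured replicate 1, 2 or 3 the call ended, at -0.507, -0.698 and -0.554 (exact permutation, adjusted p = 0.109 each), as 9 against 2 cannot go below p = 0.0182. With genes chosen at P12 instead, that difference was -0.0940 (exact permutation, adjusted p = 0.618). Injured libraries at P7 in the intravenous experiment lay 0.957 above control, and treated ones 0.0672 below injured (exact permutation p = 0.573). Injured against control cannot go below an exact permutation p of 0.1 with 3 against 3, the value it had in both P7 experiments. At P12 and P22 the score did not separate injured from control libraries (0.0541, -0.00779, 0.416 and 0.235, exact permutation p from 0.2 to 1), so its treatment differences, from -0.442 to 0.135 and not called, say little.

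**Figure D5:**
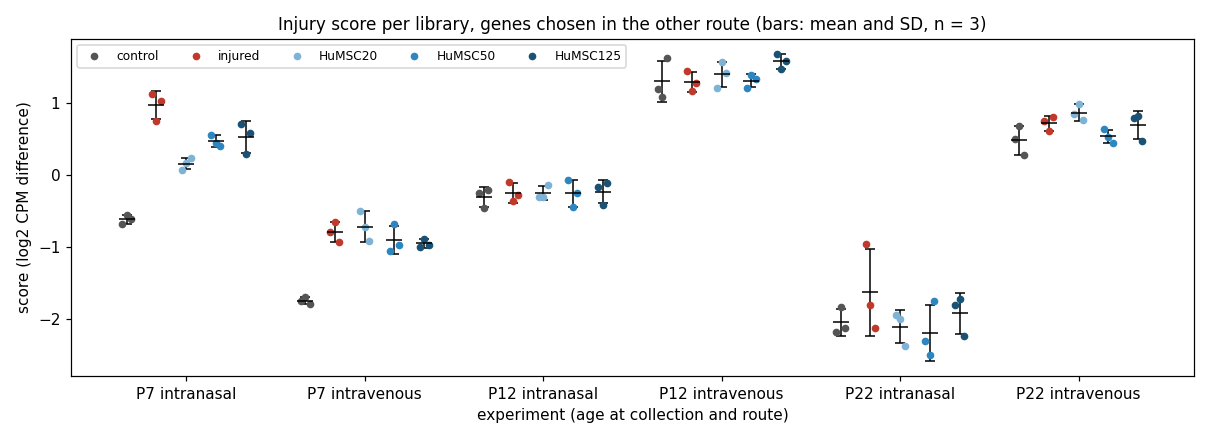
Injury score (y axis, log2 CPM difference) per library, by experiment (x axis) and arm (colour); points are libraries, and dashes with bars are the mean and SD of 3. At P7 in the intranasal experiment injured libraries averaged 0.971 and control libraries -0.615.

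Effects were also correlated across genes, which are not independent replicates, over 12 relations that share no library. Injury effects of the 2 routes at P7 correlated with r = 0.413 and rho = 0.430 (permutation p = 0.010, adjusted p = 0.08, permutations of library labels). With 3 against 3 in both experiments 0.010 is the smallest p for this relation, as the observed r was the highest of the permuted ones too, so it could not pass adjustment over 12 alone. At P12 and P22 r was -0.126 and 0.161, with rho = -0.0694 and 0.224 (permutation p = 0.441 and 0.337, adjusted p = 0.529 and 0.506). Treatment effects of the 2 routes had r = -0.0356, -0.152 and 0.452 at P7, P12 and P22, the last with rho = 0.511 (permutation p = 0.020, adjusted p = 0.08). Treatment at P7 by the intranasal route against injury in the intravenous experiment gave r = -0.229 and rho = -0.160 (permutation p = 0.017, adjusted p = 0.08). The other 5 relations of that kind had r from -0.197 to 0.269, the highest for intravenous treatment against intranasal injury at P12 (permutation p = 0.048, adjusted p = 0.144).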

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

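The tests of RNA carried over from neurons and oligodendrocyte-lineage cells, of donor transcripts, of library depth and of dilution of microglial RNA were chosen after the results they bear on had been seen, as was the look at B cell markers in the intravenous experiment; the fits without neuron-rich libraries were added then too. The results below were set apart because effects of the same contrast differed between ages or routes in a test of the difference itself.

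For the injury effect, 28 genes differed between routes at P12, and 1, 1 and 0 did so without replicate 1, 2 and 3 of every group. Between ages 169 genes differed for P12 against P7 (12, 21 and 22 without replicate 1, 2 and 3), 320 for P22 against P7 (28, 39 and 58) and 3 for P22 against P12 (0, 0 and 1). The treatment effect differed between routes for 25 genes at P7 (0, 0 and 0) and 131 at P12 (29, 0 and 0). The median difference of injury effects between routes at P7, intravenous minus intranasal, was 0.78 for cell cycle genes, -0.58 for monocyte markers, -1.79 for neutrophil markers and -2.25 for mast cell markers. That of cell cycle genes between P12 and P7 was 0.67. For the treatment effect at P12 the median difference between routes was 0.74 for inflammatory cytokines and NF-kB targets, 0.21 for immunoregulatory activation markers and -0.76 for astrocyte markers.

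In the intravenous experiment at P7 949 genes rose with HuMSC125, out of 1074 called. Donor transcripts counted on rat genes would bring the genes that stromal cells express most, but the fibroblast list had a median of 0.257 where the neuron list had 3.37. By depth, the controls and HuMSC20 replicate 2 lay within the 16.0 to 27.9 M counts of HuMSC125. These 4 held the risen genes at 0.321 ± 0.189 log2 units above the injured mean (SE), against a median of 2.33 in HuMSC125. These genes stood at 2.93, 3.05 and 1.00 in HuMSC125 replicates 1, 2 and 3. HuMSC20 replicate 1, a neuron-rich library of another dose just above that range at 28.1 M, stood at 2.95, so depth is not decided. RNA of neurons and oligodendrocyte-lineage cells that the CD11b/c beads should have removed may account for the rise. Map2 was the most abundant neuron marker, at 375 CPM in HuMSC125. An effect of HuMSC stays open and untested. The other 5 treated libraries stood at 0.437 to 1.25 and the control ones at -0.0133 to 0.431, while injured ones lie around 0 by construction.

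At P12 in the intranasal experiment 128 of the 383 injury calls were also called over the mean of doses, all 128 in the opposite direction. At HuMSC20 Csf1 stood at 61.1 CPM against 88.1 in injured and 37.8 in control libraries, and Il1b at 250 against 211 and 92.9. The injured libraries enter both effects. Simulations of chance values gave covariances no lower than -0.0373, against -0.0788 observed. They drew each gene independently, so chance stays open. With the mean immediate early level of each library as a covariate 49 of the 383 calls were kept and the median size of the injury effects went from 0.72 to 0.71, while their median SE went from 0.15 to 0.20. With the oligodendrocyte marker level it went to 0.52 and 0 calls were kept, as the median SE rose to 0.36. Differences in dissociation response or in oligodendrocyte RNA between libraries therefore cannot be told apart from an effect of injury and HuMSC, since both levels moved with the groups; either may contribute, and a biological effect was not tested apart from them.

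At P7 in the intranasal experiment 33 of 43 cell cycle genes fell with injury, with a median of -0.88. Dilution of microglial RNA by other cells would lower microglial genes alike, and the homeostatic list had a median of -0.15, which argues against it. Proliferating B-lineage cells, more common in control libraries, were not decided by the level of Ighm, their most abundant marker there, at 55.0 CPM (the other 4 between 2.11 and 18.8) where the median cell cycle gene stood at 80.7 CPM. They were argued against as the whole cause by the intravenous experiment at P7, where B cell markers had a mean change of -0.55 ± 0.11, against -0.67 ± 0.17 in the intranasal one, and cell cycle genes one of -0.0678 ± 0.0746 where -0.61 would be in proportion (SE, n = 3 against 3). A slower division of microglia after IL-1β stays open and was not tested.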

How the results depend on the processing

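Counts, scores and correlations were set against the alternatives made for them, named genes against RLE size factors, DESeq2, the block and fits without 1 library, and lists against RLE size factors, the block and an estimated correlation. Counts below are those that moved by more than 1.5 times, while fits without 1 library are all given as ranges. The cause of each shift was not tested. Of 80 named gene results that were called, 45 kept their call in every fit without 1 library and 35 lost it in at least 1, and 0 of all 85 turned direction. RLE size factors ended 0 of these calls, and DESeq2 0. Of 47 named list results, 38 lost their camera call with an estimated correlation and 9 stayed as they were.

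With DESeq2 the counts at P7 intranasal were 1259 for injured, 90 for HuMSC20, 20 for HuMSC50, 47 for HuMSC125, 106 for the mean of doses, 1014 for treated against control and 6 among doses. At P7 intravenous they were 58 for injured, 756 for HuMSC20, 17 for HuMSC50, 1048 for the mean of doses, 1391 for treated against control and 21 among doses. At P12 intranasal they were 826 for injured, 67 for HuMSC20, 379 for HuMSC50, 408 for HuMSC125, 425 for the mean of doses, 127 for treated against control and 147 among doses. At P12 intravenous they were 31 for injured, 18 for HuMSC20, 57 for HuMSC50, 65 for HuMSC125, 62 for the mean of doses, 853 for treated against control and 158 among doses. At P22 intranasal they were 7 for injured, 20 for HuMSC20, 20 for HuMSC50, 125 for HuMSC125, 147 for the mean of doses, 16 for treated against control and 41 among doses. At P22 intravenous they were 191 for injured, 4 for HuMSC20, 1550 for HuMSC50, 294 for HuMSC125, 309 for the mean of doses, 1549 for treated against control and 544 among doses. Between experiments they were 63 and 122 for the injury effect between routes at P7 and P12. They were 337 for P12 against P7, 636 for P22 against P7, 122 for P22 against P12, and 614 and 319 for the treatment effect between routes at P7 and P12. In simulated data DESeq2 made more false calls than edgeR, up to 22.6 percent against up to 7.25 percent.

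Without the filter on low counts the counts at P7 intranasal were 32 for HuMSC20 and 4 for HuMSC50. At P7 intravenous they were 367 for treated against control. At P12 intranasal they were 4 for HuMSC20, 260 for HuMSC125 and 101 among doses. At P12 intravenous they were 16 for injured, 6 for HuMSC20, 31 for HuMSC50, 23 for HuMSC125, 30 for the mean of doses and 62 among doses. At P22 intranasal they were 1 for injured, 8 for HuMSC125, 2 for the mean of doses and 2 among doses. At P22 intravenous they were 9 for injured, 3 for HuMSC125, 23 for the mean of doses and 3 among doses. Between experiments they were 1 for the injury effect between routes at P7, 15 for that effect at P12 and 94 for the treatment effect between routes at P7.

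In a fit of only the 2 groups compared the counts at P7 intranasal were 402 for injured, 41 for HuMSC20, 0 for HuMSC50 and 1 for HuMSC125. At P7 intravenous they were 58 for injured, 3 for HuMSC50 and 673 for HuMSC125. At P12 intranasal they were 89 for injured, 0 for HuMSC20 and 3 for HuMSC125. At P12 intravenous they were 0 for injured, 1 for HuMSC20 and 29 for HuMSC50. At P22 intranasal they were 1 for injured, 1 for HuMSC20 and 0 for HuMSC125. At P22 intravenous they were 0 for injured and 2 for HuMSC125.

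The replicate number was used as a block, though it did not pair libraries: in 0 of 24 comparisons did all same-number pairs correlate above 0.1, and r ran from -0.310 to 0.316. With that block the counts at P7 intranasal were 4 for HuMSC20 and 0 for HuMSC50. At P7 intravenous they were 2 for injured and 48 for treated against control. At P12 intranasal they were 13 among doses. At P12 intravenous they were 8 for HuMSC50, 555 for treated against control and 2 among doses. At P22 intranasal they were 0 for HuMSC125. At P22 intravenous they were 225 for HuMSC50, 0 for HuMSC125, 0 for the mean of doses and 64 for treated against control. Between experiments they were 6 for the injury effect between routes at P12, 0 for P22 against P12 and 0 for the treatment effect between routes at P7. Control groups by age gave 4531 (intranasal), 4766 (intravenous) and 3128 (both). Of named gene results 10 lost their call with the block.

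With RLE size factors the counts at P7 intranasal were 2 for HuMSC50. Without the libraries rich in neuron markers the count among doses at P12 intranasal was 66. At P7 intravenous 1 HuMSC125 library was left in that fit, so counts that use this dose are not given. The fit was added after the marker levels had been seen.

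Leaving out 1 library gave counts at P7 intranasal of 231 to 761 for injured, 0 to 14 for HuMSC20, 0 to 3 for HuMSC50, 0 to 0 for HuMSC125, 0 to 20 for the mean of doses, 59 to 584 for treated against control and 0 to 3 among doses. At P7 intravenous they were 2 to 5 for injured, 0 to 662 for HuMSC20, 0 to 1 for HuMSC50, 0 to 2127 for HuMSC125, 0 to 1040 for the mean of doses, 14 to 1242 for treated against control and 0 to 1 among doses. At P12 intranasal they were 68 to 452 for injured, 0 to 3 for HuMSC20, 29 to 143 for HuMSC50, 28 to 175 for HuMSC125, 41 to 243 for the mean of doses, 0 to 7 for treated against control and 2 to 66 among doses. At P12 intravenous they were 0 to 6 for injured, 0 to 5 for HuMSC20, 0 to 12 for HuMSC50, 0 to 4 for HuMSC125, 3 to 19 for the mean of doses, 26 to 749 for treated against control and 0 to 4 among doses. At P22 intranasal they were 0 to 1 for injured, 0 to 0 for HuMSC20, 0 to 0 for HuMSC50, 0 to 4 for HuMSC125, 0 to 7 for the mean of doses, 1 to 3 for treated against control and 0 to 1 among doses. At P22 intravenous they were 0 to 7 for injured, 0 to 0 for HuMSC20, 1 to 844 for HuMSC50, 0 to 2 for HuMSC125, 0 to 42 for the mean of doses, 4 to 1043 for treated against control and 0 to 83 among doses. Leaving out 1 replicate number of every group gave 0 to 0, 0 to 1 and 0 to 11 for the injury effect between routes at P7, P12 and P22. It gave 12 to 22 for P12 against P7, 28 to 58 for P22 against P7 and 0 to 1 for P22 against P12. Control groups by age gave 5584 to 7144 (intranasal), 5300 to 6648 (intravenous) and 3961 to 4813 (both). The treatment effect between routes gave 0 to 0, 0 to 29 and 0 to 0 at P7, P12 and P22.

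With genes chosen at another age the scores of injured minus control and of treated minus injured were 0.461 and -0.0940 at P7 intranasal, 0.566 and -0.0749 at P7 intravenous, 0.491 and -0.299 at P12 intranasal, 0.367 and 0.0955 at P12 intravenous, -0.121 and 0.104 at P22 intranasal and 0.0743 and 0.195 at P22 intravenous. Signs thus turned for both at P22 intranasal, for treated minus injured at P12 intranasal and P22 intravenous and for injured minus control at P12 intravenous, and no difference was called. Leaving out 1 library gave injury scores, for injured minus control and for treated minus injured, of 1.51 to 1.70 and -0.698 to -0.507 at P7 intranasal, 0.889 to 1.03 and -0.137 to 0.000785 at P7 intravenous, -0.0248 to 0.112 and -0.0559 to 0.0791 at P12 intranasal, -0.114 to 0.155 and 0.0696 to 0.209 at P12 intravenous, 0.0814 to 0.664 and -0.690 to -0.107 at P22 intranasal and 0.130 to 0.332 and -0.0771 to 0.0244 at P22 intravenous. Across genes with a mean log2 CPM of at least 3, r between routes was 0.609 for injury at P7, -0.0553 at P12 and 0.299 at P22, and 0.0243 for treatment at P7. Between treatment and the injury effect of the other route it was 0.0448 for intravenous treatment at P7, 0.0576 for intranasal treatment at P12, -0.321 for intravenous treatment at P22 and -0.334 for intranasal treatment at P22, and within P12 intravenous it was -0.331.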

Other observations

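Control microglia differed between P22 and P7. Age goes with run and dissociation kit here, so the values below describe all of them together, for P22 minus P7 in the intranasal and then the intravenous experiment. Cell cycle genes were lower at P22 for 42 and 42 of 43, with medians of -4.04 and -4.00 (adjusted p = 9.92e-07 and 2.63e-06 with an estimated correlation). Homeostatic microglial genes were higher for 19 and 19 of 25, with medians of 0.99 and 0.97 (adjusted p = 0.0412 and 0.0235 with an estimated correlation). Complement and phagocytosis genes were higher for 17 and 17 of 27 and lower for 4 and 3 (adjusted p = 0.0487 and 0.0182 with an estimated correlation). Microglial maturation markers were higher for 13 and 10 of 19 (adjusted p = 0.0804 and 0.237 with an estimated correlation). Disease-associated and axon-tract genes, which mark microglia of early postnatal white matter, were lower for 18 and 14 of 29 and higher for 5 and 7 (adjusted p = 0.320 and 0.606 with an estimated correlation). Oligodendrocyte markers were higher for 16 and 16 of 17, with medians of 3.73 and 3.55 (adjusted p = 0.0412 and 0.0769 with an estimated correlation). In both routes 5635 genes were called in the same direction, 2724 higher and 2911 lower (edgeR, 3 control libraries per experiment).

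The other gene lists went as follows between those control groups, given as genes higher and lower over all genes tested in each route. Counts adjusted over the list alone differed from these by at most 3 genes in any of the 35 lists. Inflammatory genes had 4 higher and 17 lower of 29, then 5 and 12, interferon response 6 higher and 10 lower of 40, then 9 and 8, antigen presentation 8 higher and 3 lower of 20, then 11 and 1, and cytotoxic or pro-inflammatory markers 3 higher and 3 lower of 8, then 3 and 3. Repair or anti-inflammatory markers had 2 higher and 5 lower of 12, then 2 and 3, and immunoregulatory markers 4 higher and 3 lower of 11, then 6 and 2. Cholesterol synthesis had 1 higher and 8 lower of 25, then 1 and 8, LXR targets 3 higher and 7 lower of 17, then 3 and 7, glycolysis and hypoxia 7 higher and 10 lower of 23, then 8 and 7, and glucocorticoid response 4 higher and 8 lower of 16, then 9 and 4. Oxidative phosphorylation had 0 higher and 41 lower of 45, then 0 and 32, ribosomal proteins 0 higher and 33 lower of 38, then 0 and 31, mitochondrially encoded transcripts 0 higher and 11 lower of 13, then 0 and 4, and immediate early genes 2 higher and 16 lower of 32, then 4 and 16. Camera calls in this group that an estimated correlation ended had adjusted p = 0.495 and 0.707 (inflammatory genes), 0.495 and 0.228 (antigen presentation), 0.495 and 0.707 (oxidative phosphorylation), 0.495 and 0.700 (ribosomal proteins) and 0.520 and 0.707 (immediate early genes) with an estimated correlation.

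Among markers of other cells, border-associated macrophages had 1 higher and 7 lower of 13, then 2 and 3, monocytes 7 higher and 1 lower of 12, then 6 and 2, neutrophils 15 higher and 0 lower of 16, then 10 and 0, and T and NK cells 5 higher and 4 lower of 12, then 6 and 4. B cell markers had 2 higher and 3 lower of 5, then 1 and 3, dendritic cell 5 higher and 0 lower of 8, then 6 and 0, erythroid 0 higher and 0 lower of 10, then 8 and 1, and mast cell 1 higher and 5 lower of 11, then 0 and 10. Neuron markers had 1 higher and 7 lower of 20, then 0 and 15, astrocyte 4 higher and 1 lower of 16, then 1 and 8, and oligodendrocyte precursor 4 higher and 2 lower of 12, then 1 and 8. Endothelial markers had 10 higher and 0 lower of 16, then 7 and 1, mural 2 higher and 0 lower of 12, then 4 and 3, fibroblast 1 higher and 4 lower of 12, then 1 and 2, and ependymal and choroid plexus 2 higher and 0 lower of 12, then 1 and 0. No marker list other than that of oligodendrocytes passed in either route with an estimated correlation; adjusted p was 0.495 and 0.606 for neutrophils, 0.495 and 0.707 for endothelial cells, 0.701 and 0.228 for neurons, 0.849 and 0.700 for mast cells, 0.849 and 0.647 for oligodendrocyte precursors and 0.495 and 0.374 for dendritic cells with an estimated correlation.

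Treatment and injury effects within an experiment share the injured libraries, so their correlation across genes lies below 0 without any effect. The observed r was -0.585, -0.254, -0.687, -0.488, -0.756 and -0.309 for P7 intranasal, P7 intravenous, P12 intranasal, P12 intravenous, P22 intranasal and P22 intravenous, against simulated means of -0.614, -0.603, -0.602, -0.592, -0.624 and -0.611. The covariance was further from 0 than the simulated mean at P7 intranasal (-0.0541 against -0.0324), P12 intranasal (-0.0788 against -0.0353), P12 intravenous (-0.0361 against -0.0266) and P22 intranasal (-0.0842 against -0.0434). It was nearer to 0 at P7 intravenous (-0.0381 against -0.0573) and P22 intravenous (-0.0341 against -0.0383). The part of these covariances that comes from the 3 shared libraries cannot be split off.

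Other splits of the same libraries were used to see which counts could arise by chance. For 3 against 3 the 10 splits are too few to tell. The real count and the highest of the other splits were 772 and 0, 15 and 0, 1 and 3, and 0 and 20 for injured, HuMSC20, HuMSC50 and HuMSC125 at P7 intranasal. They were 5 and 0, 0 and 0, 0 and 0, and 1074 and 0 at P7 intravenous, and 383 and 0, 1 and 0, 169 and 0, and 146 and 1 at P12 intranasal. They were 2 and 0, 3 and 3, 5 and 1, and 4 and 2 at P12 intravenous, 0 and 0, 0 and 0, 0 and 0, and 2 and 0 at P22 intranasal, and 1 and 0, 0 and 0, 718 and 0, and 1 and 0 at P22 intravenous. What set apart the split that called 20 genes was not tested.

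With 21 splits a count that no other split reached has a share of 1 in 21. This was not adjusted over the many comparisons, so some such counts can arise by chance. No other split gave as many genes for the mean of doses against injured at P7 intranasal (18, highest other 5), P12 intranasal (225 and 2) and P22 intravenous (3 and 1). Nor did any for the mean of doses against control at P7 intranasal (416 and 1), P12 intravenous (346 and 9) and P22 intravenous (505 and 1). In the joint fits the same held for the injury effect between routes at P12 (28 and 1) and between ages (169 and 23, 320 and 6, 3 and 1), for the control groups (5438 in a fit of their 12 libraries, and 0), and for the treatment effect between routes at P7 (25 and 0) and P12 (131 and 1). Chance stays fully open, with at least 1 other split giving as many genes, for the mean of doses against injured at P12 intravenous (4 and 4). It does so too against control at P7 intravenous (97 and 543), P12 intranasal (7 and 468) and P22 intranasal (1 and 265). So it was for differences among doses at P12 intranasal (33 and 57), P12 intravenous (1 and 1) and P22 intravenous (1 and 2). Where the real count is 0 every split gives as many, so splits decide nothing there. Some splits called far more genes than the real one, up to 2171 among doses at P7 intravenous, and what sets those libraries apart was not tested.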
